A study of Bistorta pergracilis with 6 samples.

How the data were processed

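Root RNA was sequenced on an Illumina HiSeq instrument from 3 libraries of a dormant stage and 3 of a growth stage, per the labels. Total RNA was extracted with Trizol and libraries were made with an Illumina TruSeq kit, per the labels' protocols. The stage of each library was taken from its label, and the replicate number from its title. The labels state that roots of both stages came from the same plants and that 3 plants gave the replicates, but they do not say which number belongs to which plant.

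The authors deposited estimated read counts per unigene, which are expected counts in the sense of RSEM, and 67.9 to 69.2% of them were whole numbers. A unigene is a cluster of assembled transcripts. RSEM, DESeq 1.10.1, SAMtools 0.1.18, Picard and GATK are named in the submitters' processing notes, with no role or order. The assembler, the read filters and the thresholds of the database searches are not given in the sources used here. FPKM values per unigene were deposited as well, per the file headers, as were a table of best database hits, transcription factor families and KEGG pathways. The authors' deposited table of the comparison holds group means of normalised counts (a signal with no value per library), a log2 fold change, a p-value and an adjusted p-value per unigene. No reference genome was used here, so no coordinates are given and genes are named by the best hit in the deposited annotation, with the unigene identifier.

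Estimated counts were rounded to whole numbers. Unigenes were kept by edgeR's filterByExpr with its minimum count of 10, libraries were scaled by TMM, and growth was compared with dormancy by edgeR's quasi-likelihood F test with robust fitting (edgeR 4.0.16, R 4.3.3), with stage as the only term. Adjusted p-values are Benjamini-Hochberg values over the 115390 unigenes tested, and a unigene was called at an adjusted p under 0.05. Log2 fold changes are growth over dormancy, so a positive value is higher in growth. CPM values were computed by edgeR's cpm function on TMM-scaled library totals and are given as means over 3 libraries, with the SD where one is printed. A ratio against a stage with no count was computed against a floor of 3 counts over that stage's 3 libraries and is written as a lower bound. Floors cover counting error only, since reads without molecular identifiers are not independent molecules. Bootstrap intervals of list medians cover the spread among members of a list only. Totals of 18370000 to 26980000 counts per library set that floor.

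A total of 31 gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01. Camera asks whether the members of a list moved differently from the other tested unigenes. The lists were mitotic cell cycle, DNA replication and histones, cytosolic ribosomal proteins, cell wall loosening and primary wall, secondary wall and xylem, lignin and general phenylpropanoid enzymes, flavonoid biosynthesis enzymes, starch synthesis, starch breakdown, sucrose cleavage and synthesis, raffinose family oligosaccharides, late embryogenesis abundant (LEA), dehydrin and cold-regulated proteins, heat shock proteins, DREB/CBF factors, abscisic acid, gibberellin, auxin, cytokinin and ethylene genes, dormancy-associated and flowering-time regulators, circadian clock and light receptors, photosynthesis, storage proteins, root hair and epidermis, endodermis and suberin, phloem, meristem identity, antioxidant enzymes, class III peroxidases, pathogenesis-related and defence proteins, and water and nutrient transport. A unigene joined a list when its description matched the list's text pattern, unless its best NR hit was outside land plants, so a list can hold regulators or inhibitors of the process it is named for. KEGG pathways and transcription factor families with at least 10 tested unigenes were tested with Fisher's exact test, one-sided per direction for pathways and two-sided for families, with Benjamini-Hochberg adjustment within each kind. The background was the tested unigenes that carry a pathway or a family. Fisher's test treats unigenes as independent, but several can carry reads of the same gene, and related genes can move together. Its p-values therefore do not measure spread among plants and may be too small. Shares of counts were compared with an exact two-sided permutation test of 3 against 3 libraries, whose smallest possible p is 0.10.

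The tests, the lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule took, per direction, the 10 unigenes with the largest fold change among called unigenes with non-overlapping stages, a mean log2 CPM of at least 4, a Swiss-Prot or KEGG orthology description and a land plant best hit in the NR database. It also took the 2 unigenes of lowest adjusted p per list and direction with a mean log2 CPM of at least 1, and the unigene of lowest adjusted p in each pathway or family that passed. The text describes a selection of these 215 unigenes, leaving out those with 1 to 3 counts in a stage. The few named outside the rule, the most abundant unigenes and the most abundant fungal ones, are marked as chosen after their values were seen.

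The class of organism was to be taken from the best NR hit. The deposited NR hits proved to be of plants, algae and oomycetes, apart from 289 unigenes with another organism, mostly protists, or none named. No genus of fungi was among them, so this rule misses fungi: the oak genus Quercus was the best NR hit of 18741 unigenes, and 76.5% of those with a Swiss-Prot hit had a fungal Swiss-Prot hit. The NR share was kept as planned, with algae counted apart because the plan did not place them, and the organism of the best Swiss-Prot hit is given beside it as an addition made after the data were seen. The same holds for a refit of the 45356 unigenes with a land plant Swiss-Prot hit that passed the filter alone, called the land plant refit here.

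Alternatives were other scalings (size factors of DESeq2, library totals), no count filter, a mean count of at least 10, DESeq2 1.42.0, limma-trend on log2(FPKM + 1), the replicate number as a block, land plant unigenes only, counts summed per Swiss-Prot entry, camera with an estimated correlation, the fry test, and each library left out in turn. The edgeR steps were tested on simulated counts for the growth and dormant comparison, drawn for 115390 unigenes from the real means and spreads with a small set changed by known folds. The simulation recovered 3.45% of the 2-fold and 23.0% of the 4-fold changes among 87 tested unigenes of each size, and 10.7% of 28 and 55.6% of 36 at a mean count of at least 100, a subset added after the low total was seen. It made 27 calls, of which 14.8% were false. So few changed unigenes make the Benjamini-Hochberg cutoff stricter than in the real comparison, where 69723 unigenes were called. These shares therefore do not give the sensitivity or the error rate of the real comparison. Annotation tables were read with Python 3.11.15 and pandas 2.3.3, figures were drawn with matplotlib 3.10.9, and tables were read in R with data.table (version 1.17.8). Deposited tables of GO and KOG terms and of predicted protein interactions were not used here.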

Results

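RNA sequencing was used to compare roots of a wild buckwheat between a winter dormant stage and a spring growth stage. The submitters name the plant Fagopyrum hailuogouense and GEO lists it as Bistorta pergracilis. Each stage had 3 libraries. The labels state that both stages were taken from the same plants and that 3 plants were the replicates, but no library number is tied to a plant, so the p-values here may measure mostly technical spread. Library totals were 21970000, 18370000 and 21310000 estimated counts for dormant replicates 1 to 3, and 22520000, 26980000 and 23640000 for growth replicates 1 to 3. Between 211204 and 216735 unigenes had a count in a dormant library, against 133640 to 137962 in a growth library. Across all tested unigenes, which are not independent replicates, Spearman correlations were 0.876 to 0.883 within dormancy, 0.936 to 0.941 within growth and 0.333 to 0.345 between the stages. The first principal component held 86.1% of the variance and separated the stages. Libraries of 1 stage differed by more than counting noise, with a mean chi-square per unigene of 8.41 to 10.98 for pairs.

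Photosynthesis, cell wall loosening, mitotic, auxin and cytokinin transcripts were higher in the growth-stage root samples, while ribosomal protein transcripts were higher in the dormant ones. Pathogenesis-related and defence unigenes moved both ways: 316 rose and 281 fell, and the list was called up (adjusted p = 1.4e-04) but not in the refit on land plant unigenes alone (adjusted p = 0.554), with the fry direction down. The aquaporin TIP1-3, a water channel of the vacuole membrane, rose from 32.6 ± 2.12 to 1080 ± 45.1 CPM (SD, n = 3), a log2 fold change of 5.05 ± 0.06 (SE). The wall protein fasciclin-like arabinogalactan protein 1 (FLA1) rose from 2.30 ± 0.195 to 119.5 ± 3.83 CPM. Pathogenesis-related protein 1B, a secreted defence protein, fell from 3192 ± 4.94 to 353.9 ± 2.35 CPM. Glutathione S-transferase U8, a detoxification enzyme, fell from 544.6 ± 4.69 to 49.9 ± 2.03 CPM. Unigenes with a fungal best Swiss-Prot hit made up 7.18% ± 0.0570 of counts in dormancy and 1.14% ± 0.00483 in growth (SD, n = 3). A list of stomatal and aerial epidermis genes was written after results were seen, with lipid, wax and YABBY genes among its abundant members. It rose in growth too, 51 of 80 unigenes with a median log2 fold change of 2.17. Green aerial tissue in the growth samples may therefore contribute to the rises above, and the part that belongs to root cells was not measured.

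The question was which transcripts differ between the dormant and the growing root. Of 289634 unigenes, 115390 were tested with edgeR, and 69723 passed an adjusted p of 0.05, of which 21301 rose and 48422 fell. Another 45667 did not pass, and 73119 had an unadjusted p under 0.05. With a fold of at least 2 added, 57526 passed, 16630 higher and 40896 lower. The stages did not overlap in 68.5% of the tested unigenes, where chance gives 10%. No count was seen in growth for 33588 tested unigenes, and none in dormancy for 5206. Without a count filter 137238 passed, and with the replicate number as a block 30030, of which 9902 were higher and 20128 lower. Under library totals alone, 28121 were higher and 42986 lower. With limma-trend on FPKM, which changes the unit and the test as well as the scaling, 32902 were higher and 43676 lower, and the land plant refit gave 9303 higher and 8116 lower. Scaling by library totals alone moved the median log2 fold change of land plant unigenes by 0.32, so small changes below are relative to the scaling used.

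Most unigenes with a fungal best hit fell: of 18199 tested, 17137 fell, 400 rose and 16030 had no count in growth. Among the 45291 tested unigenes with a land plant best hit, 11129 rose, 9327 fell and 24835 did not pass, with a median log2 fold change of 0.12. Their Spearman correlations between the stages were 0.675 to 0.682. Land plant unigenes held 64.7% ± 0.177 of counts in dormancy and 71.6% ± 0.133 in growth, animal ones 5.78% and 6.22%, and unigenes with no hit 19.4% and 18.1%. Falls were also common in the classes outside land plants and fungi. Of 9939 animal-hit unigenes 4315 fell and 2147 rose, of 4269 with another organism 2133 and 667, and of 37692 without a hit 15510 and 6958. In these classes 35.4%, 42.8% and 33.4% lay below -2 on the log2 scale, against 6.55% of land plant ones. The share planned from NR hits, non-plant organisms other than algae, was 0.0959% ± 0.00107 in dormancy and 0.0382% ± 0.00124 in growth (n = 3, exact two-sided permutation p = 0.10, the smallest this design allows), and it was higher in growth when taken from the FPKM sum. Ribosomal RNA unigenes held 0.572%, 0.0908% and 0.758% of counts in dormant replicates 1 to 3 and 0.0534%, 0.0534% and 0.0563% in growth replicates 1 to 3. Unigenes with a fungal best hit that were abundant in dormancy, chosen after their values were seen, included cellobiose dehydrogenase, an enzyme of wood-decay fungi (Cluster-40288.71285, 600.3 ± 30 to 0 CPM, at least 16100-fold lower), a cellulose-growth-specific protein (Cluster-40288.77532, 404 ± 21.3 to 0 CPM, at least 10830-fold lower) and an endo-beta-1,4-glucanase (Cluster-40288.55661, 269.8 ± 16.9 to 0 CPM, at least 7237-fold lower). Others stayed expressed in growth, among them the adhesin-like PGA55 (Cluster-40288.74708, 762 to 123 CPM, log2FC -2.63 ± 0.02), a dihydrofolate reductase (Cluster-40288.70224, 392 to 187 CPM, log2FC -1.06 ± 0.024) and a casein kinase I (Cluster-40288.86781, 158 to 129.9 CPM, log2FC -0.28 ± 0.032).

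**Figure D1:**
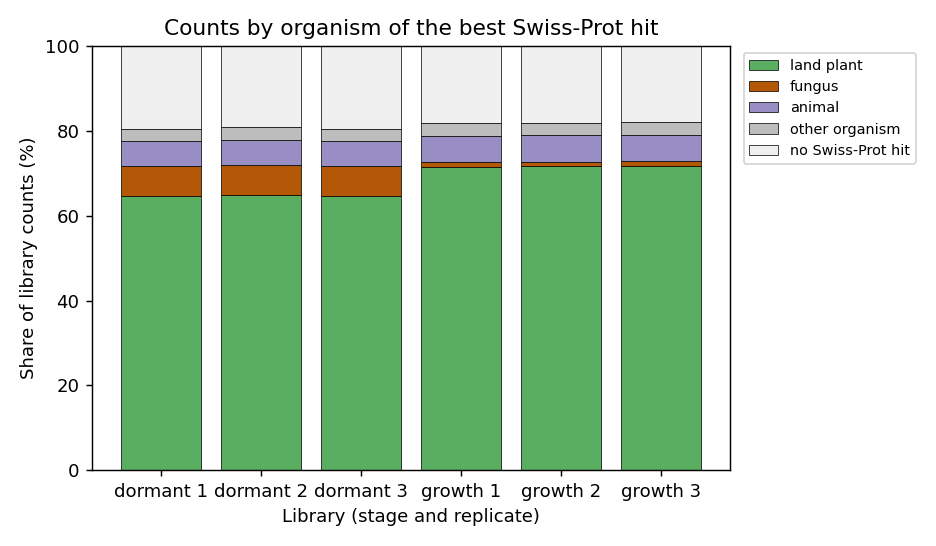
Share of estimated counts (percent, stacked bars) by the organism class of the best Swiss-Prot hit in each of the 6 libraries. The fungal part averages 7.18% in the 3 dormant libraries and 1.14% in the 3 growth libraries.

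The named unigenes below were chosen by rule, all passed an adjusted p of 0.05, and in each of them all 3 libraries of one stage lay above all 3 of the other. Values run from the dormant to the growth mean of 3 libraries, followed by the log2 fold change (log2FC) ± its standard error from edgeR, or by the SD of the 3 libraries and a bound on the fold where the other stage had no count. The largest rises were in unigenes with no dormant count, among them a mitochondrial ADP,ATP carrier (Cluster-40288.71388, 0 to 361 ± 4.82 CPM, at least 6433-fold higher), the receptor-like kinase FERONIA, which acts in cell elongation (Cluster-40288.134847, 0 to 204 ± 5 CPM, at least 3638-fold higher), chitinase 4 (Cluster-40288.69334, 0 to 77 ± 16.8 CPM, at least 1371-fold higher), the cysteine protease vignain (Cluster-40288.16065, 0 to 62.3 ± 2.49 CPM, at least 1110-fold higher) and EIN3-binding F-box protein 2, a brake on ethylene signalling (Cluster-40288.111288, 0 to 59.4 ± 3.70 CPM, at least 1058-fold higher). These need care, because reads of 1 gene can fall on several near-identical unigenes. Another tested unigene of the same Swiss-Prot entry existed for 19 of the 20 unigenes of largest change. The entry as a whole moved by less than 1 on the log2 scale for 6 of the 10 that rose and for 0 of the 10 that fell. The FERONIA entry moved by -0.04, the EIN3-binding F-box protein 2 entry by -0.12 and the chitinase 4 entry by 0.905. The ADP,ATP carrier entry fell, by -1.315, while the vignain entry rose by 3.38. The 10 of largest fall all had a land plant NR hit, as the rule requires, but only 1 had a land plant Swiss-Prot hit, glycine-rich RNA-binding protein 2 (Cluster-40288.40889, 173 ± 13.4 to 0 CPM, at least 4646-fold lower), and most of the others had a fungal one, such as the oligopeptide transporter isp4 (Cluster-40288.70959, 266 ± 8.40 to 0 CPM, at least 7136-fold lower) and the cell wall mannoprotein PIR1 (Cluster-40288.73297, 128 ± 7.32 to 0 CPM, at least 3444-fold lower).

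Camera, which compares the members of a list with all other tested unigenes, called 25 of the 31 lists at an adjusted p of 0.05, 24 up and 1 down, and 23 calls held with an estimated correlation, all but flavonoid and meristem. In the land plant refit, chosen after the data were seen, 8 lists passed, 6 up and 2 down, 7 of them among the 25. The other tested unigenes include the fungal ones, of which 94.2% fell, so the land plant refit is given beside each call. Medians and means of lists are of log2 fold changes. The fry test, which asks whether the members of a list move on balance one way, passed 27 lists, and its mixed form, which asks whether members change in either direction, passed all 31. Neither fry test compares a list with other genes.

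Most photosynthesis unigenes rose. Of 187 tested unigenes of this list, 136 rose and 3 fell (138 and 3 adjusted over the list alone). The median was 1.83 (adjusted p = 6.8e-24, adjusted p = 5.4e-18 in the land plant refit). The list held 0.988% ± 0.00996 of counts in dormancy and 4.22% ± 0.0939 in growth (n = 3, exact two-sided permutation p = 0.10, the smallest possible). Examples were a small chain of Rubisco, the carbon-fixing enzyme (Cluster-40288.74289, 225 to 1087 CPM, log2FC 2.27 ± 0.023), photosystem I subunit VI (Cluster-40288.69293, 504 to 2392 CPM, log2FC 2.25 ± 0.023) and the light-harvesting chlorophyll a-b binding protein P4 (Cluster-40288.63838, 304 to 1197 CPM, log2FC 1.98 ± 0.023). A photosystem II 10 kDa polypeptide fell (Cluster-40288.103594, 14.8 to 5.44 CPM, log2FC -1.45 ± 0.14). The list of stomatal and aerial epidermis genes moved the same way, with 51 of 80 higher and 4 lower.

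Mitotic transcripts rose and ribosomal protein transcripts fell. Of 82 mitotic cell cycle unigenes, 43 rose and 11 fell (43 and 11 adjusted over the list alone). The median was 1.44 (adjusted p = 3.6e-08, adjusted p = 4.9e-06 in the land plant refit). KNOLLE, the syntaxin that builds the cell plate, rose (Cluster-40288.45197, 0.555 to 6.86 CPM, log2FC 3.61 ± 0.20), as did CDC20.1, an activator of the anaphase-promoting complex (Cluster-40288.16254, 2.92 to 17.7 CPM, log2FC 2.60 ± 0.14), whereas a cyclin-B1-2 unigene fell (Cluster-40288.36707, 66.5 to 44.1 CPM, log2FC -0.59 ± 0.046). Among 337 unigenes of DNA replication and histones, 70 rose and 170 fell (72 and 172 adjusted over the list alone). The median was -0.64 (adjusted p = 0.303). Fungal hits made up 92 of these and all 92 fell, and in the 162 land plant members 53 rose and 33 fell (adjusted p = 0.505 in the refit). A linker histone H1 rose (Cluster-40288.56660, 72.8 to 231 CPM, log2FC 1.67 ± 0.033) and a histone H3.3 fell (Cluster-40288.58944, 392 to 183 CPM, log2FC -1.09 ± 0.037). Cytosolic ribosomal proteins formed the only list called down: of 1638 unigenes, 107 rose and 1287 fell (109 and 1295 adjusted over the list alone). The median was -7.37 (-5.04 with zero counts at the floor, adjusted p = 3.6e-11). Fungal hits supplied 744 of them, of which 741 fell. Land plant ribosomal unigenes also fell, 350 of 622 against 33 that rose, with a median of -0.72 that was -0.40 under library totals (adjusted p = 8.1e-18 in the refit). RPL10 fell (Cluster-40288.69963, 427 to 156 CPM, log2FC -1.45 ± 0.027) and RPL4-1 rose (Cluster-40288.59892, 145 to 436 CPM, log2FC 1.59 ± 0.037). Of 46 meristem identity unigenes, 15 rose and 11 fell (15 and 11 adjusted over the list alone). The median was 0.08 and the list was called up (adjusted p = 0.0170, adjusted p = 0.0503 with an estimated correlation). This call was lost without dormant replicate 1 (adjusted p = 0.0575) and in the refit (adjusted p = 0.892). SHORT-ROOT, a regulator of root radial patterning, rose (Cluster-40288.131949, 2.62 to 11.5 CPM, log2FC 2.13 ± 0.12) and the homeobox gene knotted-1-like 6 fell (Cluster-40288.73056, 21 to 6.45 CPM, log2FC -1.70 ± 0.092).

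Wall loosening genes rose more often than they fell. Of 352 unigenes of wall loosening and the primary wall, 189 rose and 62 fell (192 and 62 adjusted over the list alone). The median was 1.48 (adjusted p = 2.2e-12, adjusted p = 4.9e-08 in the land plant refit). FLA1 (Cluster-40288.16812, 2.30 to 119.5 CPM, log2FC 5.70 ± 0.068) and pectate lyase 1, a pectin-cleaving enzyme (Cluster-40288.135803, 3.88 to 66.8 CPM, log2FC 4.10 ± 0.058), rose. Expansin-like B1 (Cluster-40288.75781, 129 to 11 CPM, log2FC -3.55 ± 0.043) and a polygalacturonase inhibitor, which blocks pectin cleavage rather than carrying it out (Cluster-40288.76706, 454 to 39.5 CPM, log2FC -3.52 ± 0.037), fell. Of 87 secondary wall and xylem unigenes, 40 rose and 24 fell (41 and 24 adjusted over the list alone). The median was 1.1 (adjusted p = 3.4e-05, adjusted p = 0.153 in the refit). A pair of unigenes matching laccase-14, a lignin-polymerising enzyme, moved apart, with 1 rising (Cluster-40288.16983, 5.55 to 114 CPM, log2FC 4.37 ± 0.054) and 1 falling (Cluster-40288.74981, 369 to 56.5 CPM, log2FC -2.71 ± 0.036). Lignin and general phenylpropanoid enzymes did not pass: of 283 unigenes, 65 rose and 89 fell (64 and 86 adjusted over the list alone). The median was -0.21 and the mean -0.24, while camera pointed up (adjusted p = 0.0580) and fry down (adjusted p = 1.5e-05). Their land plant median of -0.09 became 0.24 under library totals, and in the refit camera pointed down without passing (adjusted p = 0.284). The upward camera call passed without growth replicate 1, 2 or 3 (adjusted p = 0.0283, 0.0431 and 0.0475). Caffeic acid 3-O-methyltransferase (Cluster-40288.75399, 1340 to 405 CPM, log2FC -1.73 ± 0.026) and cinnamyl alcohol dehydrogenase 1 (Cluster-40288.68503, 224 to 21.4 CPM, log2FC -3.39 ± 0.05) fell, and cinnamyl alcohol dehydrogenase 9 rose (Cluster-40288.49745, 17.7 to 72.1 CPM, log2FC 2.02 ± 0.034). Of 132 flavonoid enzymes, 37 rose and 35 fell (37 and 35 adjusted over the list alone). The median was -0.24, the mean 0.42 and the list was called up (adjusted p = 0.0185, adjusted p = 0.0503 with an estimated correlation). In the refit it pointed down without passing (adjusted p = 0.476), and the land plant median was 0.08 under library totals. The KEGG flavonoid pathway, a different set of unigenes, was called for more higher ones in both fits. It had 47 higher and 26 lower of 123 (Fisher test adjusted p = 1.7e-07, 3.3e-05 in the land plant refit). Anthocyanidin 3-O-glucosyltransferase 2 rose (Cluster-40288.67640, 113 to 1519 CPM, log2FC 3.75 ± 0.059), while the earlier pathway enzymes flavonoid 3',5'-hydroxylase (Cluster-40288.66677, 527 to 123 CPM, log2FC -2.10 ± 0.021) and naringenin 3-dioxygenase (Cluster-40288.73681, 314 to 69.2 CPM, log2FC -2.18 ± 0.033) fell.

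Barrier and peroxidase genes were mixed. Of 70 endodermis and suberin unigenes, 27 rose and 11 fell (27 and 11 adjusted over the list alone). The median was 0.47 (adjusted p = 5.6e-05, adjusted p = 0.125 in the land plant refit). Omega-hydroxypalmitate O-feruloyl transferase (Cluster-40288.14063, 1.91 to 67.2 CPM, log2FC 5.14 ± 0.072) and CYP86B1 (Cluster-40288.8755, 9.54 to 58.2 CPM, log2FC 2.61 ± 0.051), both suberin-forming enzymes, rose. Another CYP86B1 unigene (Cluster-40288.21052, 7.67 to 0.852 CPM, log2FC -3.16 ± 0.18) and CASP-like protein 4D1 (Cluster-40288.63073, 62.9 to 33 CPM, log2FC -0.93 ± 0.033) fell. Of 94 class III peroxidases, 38 rose and 32 fell (39 and 32 adjusted over the list alone). The median was 0.20 (adjusted p = 0.00460, adjusted p = 0.504 in the refit), with cationic peroxidase 1 rising (Cluster-40288.56481, 11.4 to 187 CPM, log2FC 4.04 ± 0.036) and peroxidase 57 falling (Cluster-40288.73408, 1501 to 433 CPM, log2FC -1.79 ± 0.021). Root hair and epidermis unigenes did not pass (adjusted p = 0.0800 pointing up, adjusted p = 0.639 pointing down in the refit): of 36, 6 rose and 8 fell (5 and 8 adjusted over the list alone). The fry direction was down (adjusted p = 0.111), and the land plant median of -0.04 turned positive under library totals (0.29) and among NR land plant unigenes (0.14). Without growth replicate 3 the list passed upward (adjusted p = 0.046). The epidermal regulator WER rose (Cluster-40288.141548, 0.202 to 4.30 CPM, log2FC 4.36 ± 0.33) and ROOT HAIR DEFECTIVE 3 homolog 2 fell (Cluster-40288.151344, 3.34 to 1.23 CPM, log2FC -1.45 ± 0.22).

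Starch genes rose on balance and sucrose genes did not. Of 78 starch synthesis unigenes, 24 rose and 10 fell (23 and 10 adjusted over the list alone). The median was 0.60 (adjusted p = 4.1e-05). The call held in the land plant refit (adjusted p = 0.0409) but was lost there when the correlation was estimated (adjusted p = 0.0928 with an estimated correlation). The large subunit of ADP-glucose pyrophosphorylase, the first committed enzyme of starch synthesis (Cluster-40288.23236, 25.7 to 80.8 CPM, log2FC 1.65 ± 0.051), and isoamylase 1 (Cluster-40288.104678, 9.44 to 36.3 CPM, log2FC 1.94 ± 0.06) rose, and granule-bound starch synthase 2 fell (Cluster-40288.97128, 34.5 to 16.1 CPM, log2FC -1.1 ± 0.10). Of 147 starch breakdown unigenes, 47 rose and 24 fell (44 and 23 adjusted over the list alone). The median was 0.48 (adjusted p = 4.2e-05, adjusted p = 0.180 in the refit). Inactive beta-amylase 9, a relative without the enzyme activity, had 1 unigene that rose (Cluster-40288.84504, 0 to 221 ± 4.76 CPM, at least 3932-fold higher) and 1 that fell (Cluster-40288.84508, 307 to 59.6 CPM, log2FC -2.37 ± 0.069), and the phosphorylase L-1 rose (Cluster-40288.105633, 8.17 to 25.4 CPM, log2FC 1.64 ± 0.067). Sucrose cleavage and synthesis did not pass (adjusted p = 0.180 pointing up, adjusted p = 0.153 pointing down in the refit): of 83 unigenes, 12 rose and 27 fell (12 and 24 adjusted over the list alone). The median was -0.38 and the mean 0.04, and without growth replicate 3 the list passed upward (adjusted p = 0.0368). Insoluble invertase fell (Cluster-40288.80616, 207 to 86.8 CPM, log2FC -1.25 ± 0.037), sucrose-phosphate synthase rose (Cluster-40288.48815, 99.5 to 204 CPM, log2FC 1.03 ± 0.021), and sucrose synthase had 1 unigene up (Cluster-40288.9437, 2.06 to 25.1 CPM, log2FC 3.60 ± 0.091) and 1 down (Cluster-40288.83813, 310.1 to 95.5 CPM, log2FC -1.70 ± 0.029). Of 48 unigenes of raffinose family sugars, 17 rose and 8 fell (16 and 8 adjusted over the list alone). The median was 0.06 (adjusted p = 0.00298), and -0.07 in the refit (adjusted p = 0.524). Raffinose synthase-like enzyme 2 had 1 unigene that rose (Cluster-40288.135997, 14.1 to 168 CPM, log2FC 3.58 ± 0.11) and 1 that fell (Cluster-40288.144845, 7.40 to 3.48 CPM, log2FC -1.09 ± 0.20), and enzyme 6 fell (Cluster-40288.82855, 186 to 98.6 CPM, log2FC -0.92 ± 0.061). Of 46 phloem unigenes, 18 rose and 5 fell (16 and 5 adjusted over the list alone). The median was 0.34 (adjusted p = 4.8e-04, adjusted p = 0.180 in the refit) and -0.09 among NR land plant unigenes. The sugar exporter SWEET14 rose (Cluster-40288.12949, 10.3 to 24.6 CPM, log2FC 1.26 ± 0.077) and the sucrose transporter SUC3 fell (Cluster-40288.106618, 18 to 11.9 CPM, log2FC -0.59 ± 0.068). Storage proteins did not pass (adjusted p = 0.209, adjusted p = 0.760 in the refit): of 48, 13 rose and 20 fell (13 and 20 adjusted over the list alone). The median was -0.16 and the mean -0.61 against an upward camera and a downward fry direction. The land plant median of 0.33 was -0.17 among NR land plant unigenes. Bark storage protein A, a nitrogen store of woody stems, rose (Cluster-40288.135529, 0.201 to 31.5 CPM, log2FC 7.22 ± 0.21) and patatin-like protein 2 fell (Cluster-40288.74283, 423 to 172 CPM, log2FC -1.29 ± 0.023).

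Auxin and cytokinin genes were the hormone lists that rose in both fits. Of 326 auxin transport and response unigenes, 140 rose and 39 fell (139 and 39 adjusted over the list alone). The median was 0.75 (adjusted p = 1.3e-09, adjusted p = 0.00325 in the land plant refit). The efflux carrier 1c, which moves auxin out of cells (Cluster-40288.15893, 0.839 to 39.4 CPM, log2FC 5.54 ± 0.10), and the early-response repressor IAA7 (Cluster-40288.65004, 64.1 to 164 CPM, log2FC 1.35 ± 0.031) rose, and SAUR32 fell (Cluster-40288.61072, 191 to 63.5 CPM, log2FC -1.59 ± 0.032). Of 129 cytokinin unigenes, 53 rose and 8 fell (41 and 8 adjusted over the list alone). The median was 0.76 (adjusted p = 9.4e-08, adjusted p = 0.00917 in the refit). The cytokinin-activating enzymes LOG1 (Cluster-40288.2617, 0.636 to 15.9 CPM, log2FC 4.63 ± 0.10) and LOG3 (Cluster-40288.144958, 2.47 to 14.8 CPM, log2FC 2.58 ± 0.095) rose, LOG8 fell (Cluster-40288.91165, 88.1 to 51.1 CPM, log2FC -0.79 ± 0.062), and a cytokinin hydroxylase had no count in growth (Cluster-40288.126760, 8.01 ± 1.32 to 0 CPM, at least 215-fold lower). Of 56 gibberellin unigenes, 22 rose and 17 fell (22 and 17 adjusted over the list alone). The median was 0.65 (adjusted p = 0.00493, adjusted p = 0.0920 in the refit). Gibberellin-regulated protein 6 (Cluster-40288.13923, 1.35 to 34.3 CPM, log2FC 4.67 ± 0.10) and the DELLA protein GAI, a repressor of the response (Cluster-40288.67901, 104 to 174 CPM, log2FC 0.75 ± 0.031), rose, and the biosynthetic gibberellin 20 oxidase 2 fell (Cluster-40288.74912, 33.6 to 6.42 CPM, log2FC -2.39 ± 0.15). Of 170 abscisic acid unigenes, 48 rose and 23 fell (45 and 20 adjusted over the list alone). The median was 0.26 (adjusted p = 4.0e-05, adjusted p = 0.319 in the refit). ABI5, a response factor (Cluster-40288.137231, 0.166 to 8.75 CPM, log2FC 5.66 ± 0.21), and the receptor PYL9 (Cluster-40288.124420, 25.1 to 59.4 CPM, log2FC 1.24 ± 0.06) rose, and zeaxanthin epoxidase, an early enzyme of the synthesis of abscisic acid, fell (Cluster-40288.75939, 711 to 279 CPM, log2FC -1.35 ± 0.032). Of 109 ethylene unigenes, 34 rose and 32 fell (34 and 33 adjusted over the list alone). The median was 0.07 (adjusted p = 0.00971). In the refit the list pointed down without passing (adjusted p = 0.834), and the land plant median was -0.23 among NR land plant unigenes. The last enzyme of ethylene synthesis, ACC oxidase 3, rose (Cluster-40288.137709, 0.415 to 18.41 CPM, log2FC 5.46 ± 0.20) and an ACC synthase fell (Cluster-40288.66563, 367 to 73.6 CPM, log2FC -2.32 ± 0.06).

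Dormancy and clock lists were called up over all unigenes and lost the call in the land plant refit. Of 96 dormancy-associated and flowering-time regulators, 32 rose and 10 fell (31 and 10 adjusted over the list alone). The median was 0.10 (adjusted p = 4.4e-04, adjusted p = 0.494 in the refit) and -0.11 for members among NR land plant unigenes. VIN3-like protein 2, of a family that acts in vernalization (Cluster-99574.0, 0.187 to 6.97 CPM, log2FC 5.18 ± 0.19), and MOTHER of FT (Cluster-40288.127910, 22.3 to 55.1 CPM, log2FC 1.3 ± 0.055) rose. The MADS-box repressor SVP, related to the dormancy-associated genes of trees (Cluster-40288.72486, 8.89 to 1.85 CPM, log2FC -2.26 ± 0.13), and a dormancy-associated protein homolog (Cluster-40288.73294, 407 to 189 CPM, log2FC -1.11 ± 0.02) fell. Of 155 clock and light receptor unigenes, 38 rose and 24 fell (36 and 21 adjusted over the list alone). The median was 0.33 (adjusted p = 1.6e-04, adjusted p = 0.408 in the refit), with CONSTANS-LIKE 6 rising (Cluster-40288.124767, 17.5 to 103 CPM, log2FC 2.55 ± 0.039) and the clock regulator APRR5 (Cluster-40288.82048, 45.7 to 17.6 CPM, log2FC -1.38 ± 0.086) and the blue light receptor cryptochrome-2 (Cluster-40288.72934, 33.4 to 11.9 CPM, log2FC -1.49 ± 0.10) falling.

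Cold and heat protection genes moved both ways. Of 42 LEA, dehydrin and cold-regulated unigenes, 19 rose and 9 fell (19 and 9 adjusted over the list alone). The median was 0.38 (adjusted p = 0.00102, adjusted p = 0.504 in the land plant refit). The cold-regulated membrane protein COR413-PM2 rose (Cluster-40288.60744, 117 to 456 CPM, log2FC 1.96 ± 0.024) and Lea5-D fell (Cluster-40288.71418, 836 to 602 CPM, log2FC -0.47 ± 0.036). Of 20 DREB/CBF factors, which switch on cold and drought genes, 8 rose and 3 fell (8 and 3 adjusted over the list alone). The median was 0.63 (adjusted p = 0.00335, adjusted p = 0.176 in the refit). DREB3 rose (Cluster-40288.2395, 0.853 to 10.3 CPM, log2FC 3.58 ± 0.27) and DREB2A fell (Cluster-40288.14701, 16.6 to 7.24 CPM, log2FC -1.20 ± 0.12). Of 517 heat shock protein unigenes, 216 rose and 238 fell (217 and 240 adjusted over the list alone). The median was -0.29 and the mean -0.19, while the list was called up (adjusted p = 0.00799). Fungal hits made up 217 of them, of which 148 fell, and of 187 land plant members 83 rose and 48 fell, with a median of 0.52 (adjusted p = 0.0920 in the refit). A class I small heat shock protein (Cluster-40288.84133, 1.66 to 168 CPM, log2FC 6.66 ± 0.067) and a chloroplastic one (Cluster-40288.134307, 0.116 to 409 CPM, log2FC 11.76 ± 0.14) rose, and the constitutive chaperone Hsc70-2 fell (Cluster-40288.83321, 337 to 59.3 CPM, log2FC -2.51 ± 0.041).

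Antioxidant and defence transcripts were among the most abundant of the dormant root. Of 380 antioxidant enzymes, 76 rose and 183 fell (77 and 183 adjusted over the list alone). The median was -0.72 (adjusted p = 0.615). The 81 fungal hits among them all fell, and of 267 land plant members 58 rose and 91 fell, a list called down in the refit (adjusted p = 0.0482, adjusted p = 0.0832 with an estimated correlation) whose median of -0.22 became 0.11 under library totals. Glutathione S-transferase U8 (Cluster-40288.73997, 545 to 49.9 CPM, log2FC -3.45 ± 0.036) and another glutathione S-transferase (Cluster-40288.76285, 1363 to 189 CPM, log2FC -2.85 ± 0.02) fell, and dehydroascorbate reductase 1 rose (Cluster-40288.30969, 23.2 to 113 CPM, log2FC 2.27 ± 0.044). Of 1047 pathogenesis-related and defence unigenes, 316 rose and 281 fell (313 and 278 adjusted over the list alone). The median was 0.29 and the list was called up (adjusted p = 1.4e-04, adjusted p = 0.554 in the refit), while the fry direction was down (adjusted p = 0.00522). PR-1B (Cluster-40288.93804, 3192 to 354 CPM, log2FC -3.17 ± 0.013) and the PR-10 type allergen Mal d 1 (Cluster-40288.74323, 5366 to 1228 CPM, log2FC -2.13 ± 0.012) fell, and chitinase-like protein 1, of a family that acts in cellulose deposition, rose (Cluster-40288.62514, 128 to 648 CPM, log2FC 2.34 ± 0.034). Of 470 water and nutrient transporters, 136 rose and 116 fell (133 and 110 adjusted over the list alone). The median was 0.23, the mean -0.23 and the list was called up (adjusted p = 6.2e-04, adjusted p = 0.284 in the refit), while the fry direction was down (adjusted p = 3.5e-06). All 41 fungal hits among them fell, and 133 of 425 land plant members rose and 75 fell. The aquaporins TIP1-3 (Cluster-40288.122105, 32.6 to 1080 CPM, log2FC 5.05 ± 0.065) and PIP1-3 (Cluster-40288.64654, 40.3 to 164 CPM, log2FC 2.02 ± 0.048) rose, while potassium transporter 5 (Cluster-40288.79584, 245 to 84.1 CPM, log2FC -1.54 ± 0.046) and the high-affinity nitrate transporter component 3.2 (Cluster-40288.36345, 27.1 to 3.99 CPM, log2FC -2.76 ± 0.061) fell.

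**Figure D2:**
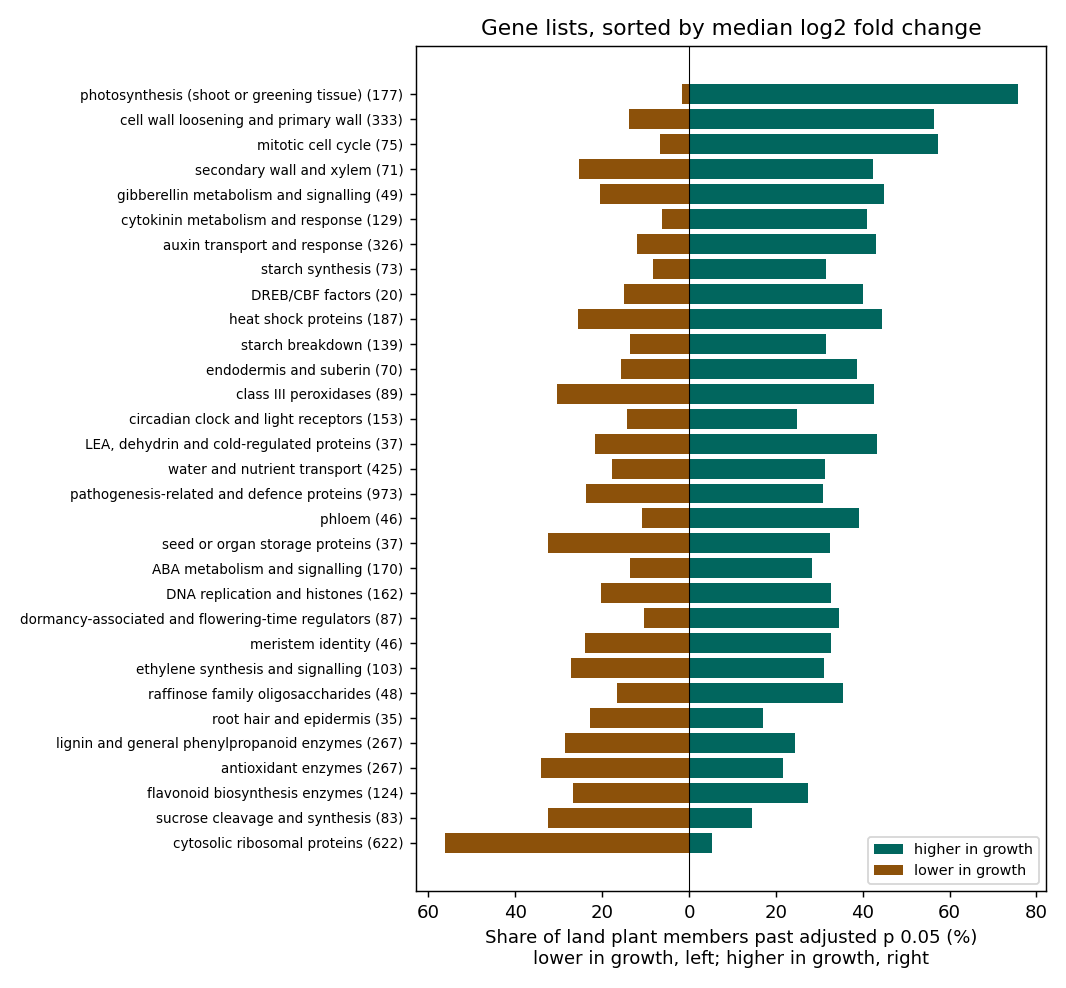
Percent of the land plant members of each of the 31 lists that passed an adjusted p of 0.05, lower in growth to the left and higher to the right, sorted by the median log2 fold change of those members, whose number is in brackets. Photosynthesis, with 134 of 177 higher, is at one end and cytosolic ribosomal proteins, with 350 of 622 lower, at the other.

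**Figure D3:**
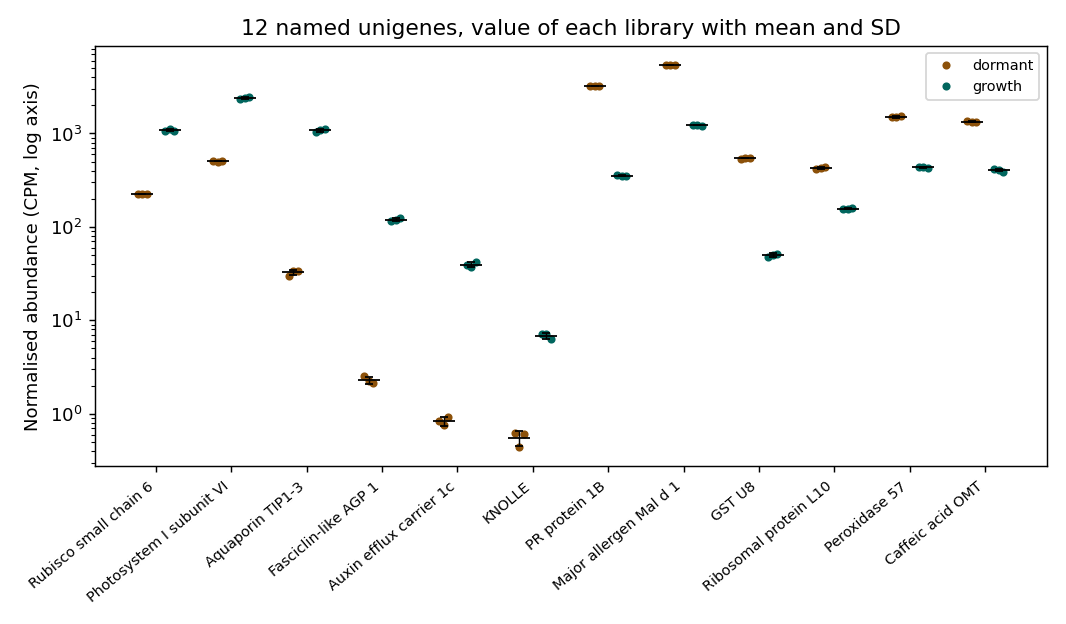
TMM-scaled CPM (log axis) of 12 named unigenes in each library, with the mean and SD of the 3 dormant and the 3 growth libraries. The stages do not overlap in any of the 12, for example TIP1-3 (32.6 to 1080) and PR-1B (3192 to 353.9).

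KEGG pathways, 127 in number, gave 38 calls for more higher unigenes than the background and 21 for more lower ones with one-sided Fisher tests. In the land plant refit 29 and 7 passed, of which 27 and 6 were also called over all unigenes. Each call compares a pathway with the background, so members that fell can outnumber those that rose. A pathway can be called in both directions, as tryptophan metabolism was (adjusted p = 0.0140 for higher and 0.00434 for lower). The tests count unigenes as independent, although several can carry reads of the same gene. The adjusted p-values may therefore be too small and do not measure spread among plants. Photosynthesis had 84 higher and 5 lower of 123 (adjusted p = 1.1e-34, 3.0e-22 in the land plant refit) and antenna proteins 38 higher and 2 lower of 57 (adjusted p = 2.4e-15, 3.9e-13 in the land plant refit). Plant hormone signal transduction had 219 higher and 142 lower of 749 (adjusted p = 2.8e-16, 6.9e-07 in the land plant refit) and phenylpropanoid biosynthesis 134 higher and 143 lower of 431 (adjusted p = 3.1e-12, 1.3e-06 in the land plant refit). The surface lipid pathway of cutin, suberine and wax had 28 higher and 12 lower of 43 (adjusted p = 3.9e-11, 2.3e-07 in the land plant refit), with the cutin enzyme glycerol-3-phosphate acyltransferase 6 among them (Cluster-40288.134388, 1.62 to 63.4 CPM, log2FC 5.28 ± 0.11). Brassinosteroid biosynthesis had 16 higher and 2 lower of 27 (adjusted p = 9.3e-06, 0.00126 in the land plant refit), with CYP90A1, an enzyme of that pathway (Cluster-40288.103854, 10.2 to 93.2 CPM, log2FC 3.20 ± 0.082). Carotenoid biosynthesis had 94 higher and 82 lower of 262 (adjusted p = 1.5e-12, 1.0e-05 in the land plant refit) and starch and sucrose metabolism 189 higher and 175 lower of 676 (adjusted p = 3.1e-12, 7.0e-05 in the land plant refit). Fatty acid elongation had 48 higher and 48 lower of 148 (adjusted p = 2.7e-05, 5.6e-06 in the land plant refit), with 3-ketoacyl-CoA synthase 10 (Cluster-40288.36541, 97.6 to 616 CPM, log2FC 2.66 ± 0.054).

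Calls for more lower unigenes included the ribosome pathway with 1433 lower and 182 higher of 1916 (adjusted p = 1.4e-157, 6.1e-65 in the land plant refit) and the proteasome with 271 lower and 19 higher of 373 (adjusted p = 1.1e-24, 2.0e-08 in the land plant refit). Protein processing in the endoplasmic reticulum had 816 lower and 257 higher of 1468 (adjusted p = 9.7e-14, 1.1e-10 in the land plant refit), but without a count filter it was called for more higher ones (adjusted p = 2.7e-18). The spliceosome had 681 lower and 147 higher of 1200 (adjusted p = 8.0e-14, 0.00132 in the land plant refit). Oxidative phosphorylation had 457 lower and 102 higher of 744 (adjusted p = 8.3e-17, 0.00433 in the land plant refit). The citrate cycle had 321 lower and 44 higher of 458 (adjusted p = 1.1e-24, 0.374 in the land plant refit), so its call was lost among land plant unigenes. Glutathione metabolism was called only there (adjusted p = 0.0187). Carbon metabolism had 895 lower and 325 higher of 1775 (adjusted p = 1.9e-04, 1 in the land plant refit), where it was called for more higher ones instead (adjusted p = 0.00456). Its named member, a cytosolic glyceraldehyde-3-phosphate dehydrogenase, fell (Cluster-40288.74469, 989 to 85 CPM, log2FC -3.54 ± 0.028), although glycolysis was called for more higher unigenes, with 166 higher and 338 lower of 745 (adjusted p = 4.6e-04, 0.0254 in the land plant refit). The proton pump plasma membrane ATPase 4 (Cluster-40288.76563, 738 to 360.1 CPM, log2FC -1.04 ± 0.016) and the chaperone calnexin (Cluster-40288.58620, 195 to 50.1 CPM, log2FC -1.96 ± 0.029) also fell.

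Transcription factor unigenes numbered 6181, of which 1322 rose and 2305 fell, and 33 of 68 families departed from that split with a two-sided Fisher test. Among land plant unigenes 980 of 4121 rose and 608 fell, and 7 families departed from that split, 5 of them also called over all unigenes. As for the pathways, unigenes were counted as independent, so the adjusted p-values of families may be too small. In AUX/IAA, auxin-response repressors, 43 rose and 3 fell of 84 (adjusted p = 8.7e-15, adjusted p = 2.9e-05 in the refit). In the B3-type family ABI3VP1 41 rose and 3 fell of 90 (adjusted p = 4.5e-14, adjusted p = 0.00272 in the refit) and in zf-HD 20 rose and 0 fell of 23 (adjusted p = 1.8e-08, adjusted p = 0.00897 in the refit). In the homeobox family 69 rose and 55 fell of 226 (adjusted p = 7.0e-05, adjusted p = 0.00897 in the refit), with the vascular regulator ATHB-8 rising (Cluster-40288.14643, 7.97 to 28.5 CPM, log2FC 1.84 ± 0.067). MADS-box unigenes, of which 35 rose and 28 fell of 89 (adjusted p = 0.00588, adjusted p = 0.0144 in the refit), included the floral regulator APETALA 1 (Cluster-40288.134379, 0.507 to 35 CPM, log2FC 6.09 ± 0.17). NAC and WRKY factors, many of them stress regulators, fell more often than they rose in the refit: NAC had 17 higher and 54 lower (adjusted p = 3.0e-09, 0.110 over all unigenes) and WRKY 30 higher and 66 lower (adjusted p = 2.4e-08, 0.557 over all unigenes). The fungal-type Zn-clus family had 301 of 302 lower (adjusted p = 4.2e-59). MYB39, a suberin regulator (Cluster-40288.144539, 0.468 to 29.9 CPM, log2FC 5.98 ± 0.16), and the brassinosteroid response factor BRASSINAZOLE-RESISTANT 1 (Cluster-40288.139260, 1.99 to 28.1 CPM, log2FC 3.82 ± 0.085) rose, and ZAT11 fell (Cluster-40288.53088, 37.5 to 9.01 CPM, log2FC -2.06 ± 0.059).

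The authors' deposited comparison of the same libraries, which is not independent, listed 138595 unigenes past its adjusted p, 31810 higher and 106785 lower in growth. Of the 69723 unigenes called here, 69271 (99.4%) passed there with the same sign, and 0 differed in sign among those past both. Floors given here cover counting error only, and intervals of list medians cover the spread among members of a list. Gene names are best database hits of unigenes, so a named change can belong to a relative of the named gene or to another organism.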

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

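The alternatives restricted to unigenes with a land plant Swiss-Prot hit and the non-plant share by Swiss-Prot organism were chosen after the data were seen, and the others before. The count of 69723 unigenes past an adjusted p of 0.05 became 137238 (29727 higher, 107511 lower) of 279408 without a count filter, 30030 (9902 higher, 20128 lower) with the replicate number as a block, 16830 of 29971 among NR land plant unigenes, 17419 of 45356 among Swiss-Prot land plant unigenes and 20704 of 23881 with counts summed per Swiss-Prot entry. With a fold of at least 2, the count of 57526 became 125770, 22730, 13377 and 11167 under the first 4 of these. Testing more, fewer or merged unigenes accounts for part of each change except that of the block, which tested the same 115390 unigenes. Deviations from the stage mean correlated by only 0.0018 to 0.0078 between dormant and growth libraries of the same number, so the block captured little shared variation. The block also leaves fewer residual degrees of freedom than stage alone, which by itself makes an adjusted p harder to pass. How much of the drop this accounts for was not tested. The block is not treated as pairing, because replicate numbers are not stated to identify plants. Called lists went from 25 to 16 (NR land plant) and 8 (Swiss-Prot land plant), and called families from 33 to 21 (block), 12 and 7. Pathway calls, counted per direction, went from 59 to 34 (NR land plant) and 36 (Swiss-Prot land plant). Of the 215 named unigenes, 80 could be tested among NR land plant unigenes and 80 passed.

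In the Swiss-Prot land plant refit, 17377 of its 17419 calls were shared with the main test in sign and 0 were opposite. With DESeq2, 69531 calls were shared of its 74323. Calls of opposite sign did occur elsewhere, 232 under library totals (64287 shared in sign) and 306 with limma-trend on FPKM (64440 shared in sign). The ethylene and flavonoid lists turned down in that refit without passing (adjusted p = 0.834 and 0.476), as did the direction of the FHA family (0.662), and the FAR1 family turned among NR land plant unigenes (adjusted p = 1); the cause was not tested. The non-plant share, -0.0577 points in the main test, was 0.0881 as a share of the FPKM sum, -0.182 with unigenes without an NR hit left out and -5.69 by Swiss-Prot organism, where the first turned direction for a cause that was not tested. Over all alternatives, named unigenes kept their call and direction in 3057 comparisons and lost the call in 10, and 0 turned. For lists the numbers were 423 and 28, with 12 newly called and 2 turned. For pathways they were 721 and 156, with 7 turned, and for families 416 and 63, with 2 turned. The named unigenes were chosen from these same libraries by low adjusted p or large fold, so their stability was partly fixed by that choice. With the replicate number as a block, 213 of the 215 named unigenes kept the call, against 29884 of all 69723 called unigenes. The pathway calls that turned, with their new adjusted p, were carbon metabolism to higher in the land plant refit (0.00456), protein processing in the endoplasmic reticulum to higher without a count filter (2.7e-18), isoquinoline alkaloid biosynthesis to lower among NR land plant unigenes (0.0412), lysine degradation to higher without dormant replicate 1 (0.0328), dormant replicate 2 (0.0207) or growth replicate 2 (0.0207), and pyruvate metabolism to higher without growth replicate 2 (0.0309). With each other library left out, the adjusted p for lower was 0.0348 to 0.1065 for lysine degradation and 0.0193 to 0.0909 for pyruvate metabolism. A turned call means that the test for one direction lost its call and the separate test for the other gained one. It need not mean that members changed direction. In the main test lysine degradation had 47 higher against 39.6 expected and 127 lower against 107.5 expected. Pyruvate metabolism had 108 higher against 96.7 and 293 lower against 262.6. The cause beyond this was not tested.

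Leaving out each library in turn gave 72420 to 76140 unigenes past an adjusted p of 0.05, 62241 to 66042 with a fold of at least 2, 24 to 28 lists, 54 to 61 pathway calls, 32 to 38 families, 214 to 215 named unigenes and a non-plant share of -0.0584 to -0.0572 points. Depth sets the floor of 3 counts against which a stage without a count is read. In simulated data at these totals, 2-fold changes were recovered in 3.45% of cases and 4-fold changes in 23.0% (10.7% and 55.6% at a mean count of at least 100), and depth was not varied. Only a small set was changed there, which makes the adjusted cutoff stricter, so these shares do not give the sensitivity of the real comparison.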

Other observations

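The aerial list, the fungal abundances and the abundant unigenes in this part were chosen after results were seen, as were all tests of the fungal, photosynthesis and one-stage patterns, whereas the counts over other splits of the libraries were planned before. Defence proteins were the most abundant transcripts of the dormant root. Hevein-like preproprotein, a chitin-binding PR-4 relative (Cluster-40288.74341, 7146 to 1096 CPM, log2FC -2.71 ± 0.039), a glucan endo-1,3-beta-glucosidase, which cleaves callose and fungal glucans (Cluster-40288.74731, 6247 to 1421 CPM, log2FC -2.14 ± 0.022), chitinase 6 (Cluster-40288.74312, 5951 to 682 CPM, log2FC -3.12 ± 0.022) and thaumatin-like protein 1 (Cluster-40288.74361, 4623 to 1083 CPM, log2FC -2.09 ± 0.023) all fell. Secoisolariciresinol dehydrogenase, an enzyme of lignan synthesis, fell with them (Cluster-40288.75400, 2915 to 903 CPM, log2FC -1.69 ± 0.02). Among the most abundant transcripts of the growing root, a trypsin inhibitor whose best hit is a buckwheat protein rose (Cluster-40288.69399, 62.9 to 2357 CPM, log2FC 5.23 ± 0.07), as did the dehydration-responsive protein RD22 (Cluster-40288.80604, 312 to 1913 CPM, log2FC 2.62 ± 0.081), abscisic stress-ripening protein 2 (Cluster-40288.87309, 692 to 1545 CPM, log2FC 1.16 ± 0.032) and MLP-like protein 423 (Cluster-40288.88153, 2.92 to 1511 CPM, log2FC 9.01 ± 0.17). Catalase 2, a peroxide-removing enzyme, moved less (Cluster-40288.73219, 1394 to 1696 CPM, log2FC 0.28 ± 0.02).

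Fungal-hit unigenes were lower in growth, and fungal RNA carried by the dormant samples may be the reason, which stays open. Fungal-hit ribosomal protein unigenes had a median log2 fold change of -6.47 (744 unigenes with zero counts at the floor, 95% bootstrap interval -6.59 to -6.37), but they are part of the set that fell, so this is no separate test. Plant transcripts that merely match a fungal entry best would be thought to move like other plant transcripts. Of fungal-hit unigenes, 93.3% lay below -2 on the log2 scale against 6.55% of land plant ones. That share restates the fall of the same unigenes, so it is no separate test either. Plant transcripts with a fungal best hit thus stay open, above all for those that stayed expressed in growth. Lower depth in growth is argued against, since the lowest growth total was 1.025 times the highest dormant one. Whether the roots carried more fungus in winter or the samples differed in handling was not tested, because the design has 1 sampling per stage.

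Photosynthesis unigenes were higher in growth, which may come from green aerial tissue collected with the growth-stage roots. The list of stomatal and aerial epidermis genes rose as that explanation predicts, with a median log2 fold change of 2.17 (80 unigenes, 51 of them higher, 30 at 1 CPM or more in dormancy, 0 in another list). FAMA and protodermal factor 1, seen before the list was written, were left out. The most abundant members were then lipid and wax genes, MERISTEM L1 and YABBY unigenes, and none of these was a stomatal gene. Examples were 3-ketoacyl-CoA synthase 5 (Cluster-40288.83908, 74 to 245 CPM, log2FC 1.73 ± 0.047) and CER26-like (Cluster-40288.28675, 17.9 to 79.9 CPM, log2FC 2.15 ± 0.11). Greening of root cells alone predicts no rise, and the lower bound of the 95% bootstrap interval, 1.66, argues against it as far as these genes are specific to aerial epidermis and were not chosen for rising. The list holds YABBY unigenes, a family called higher in the main test (18 higher and 3 lower of 28, Fisher test adjusted p = 3.4e-05). Part of the rise of the list may thus have been fixed by its choice. The KEGG pathways of cutin, suberine and wax (28 higher and 12 lower of 43) and of fatty acid elongation (48 and 48 of 148) were also called for more higher unigenes. Whether the lipid and wax genes of the list mark aerial tissue was not tested. Scaling is not the cause of the rise, since the photosynthesis median was 2.15 under library totals against 1.83 in the main test. Other lists that rose in growth, such as auxin, wall loosening and mitosis, could share this source, and the part of them that belongs to root cells was not measured.

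Unigenes of land plants with many counts in one stage and none in the other, 290 in number (194 without a dormant and 96 without a growth count), may be 1 gene whose reads moved between near-identical unigenes. Summed per Swiss-Prot entry, 54.5% of them moved by less than 1 on the log2 scale, but so did 81.9% of other land plant unigenes, and the rule for this test was changed to leave the question undecided after that baseline was seen, so the explanation cannot be told apart from a change of the gene itself. Of the 290, 279 had another tested unigene of the entry, which keeps it open. A test of too little depth says nothing here: 100% of them lay at least 16-fold above the floor of 3 counts, which their choice by a minimum abundance had fixed. No biological explanation was tested.

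The 6 libraries can be divided into 3 and 3 in 10 ways, too few for a share under 0.05, and in each count below 1 split, the real one, gave a result as large. The real split gave 69723 unigenes past an adjusted p of 0.05, and the highest other split 0. For a fold of at least 2 the counts were 57526 and 0, for gene lists 25 and 19, for KEGG pathway calls 59 and 0, and for transcription factor families 33 and 0. Splits that mix the stages still called 15 to 19 lists. Each of them sets 2 libraries of a stage against 1, so part of the stage difference remains in them. They therefore cannot show how many lists camera would call without a stage difference, and the number of called lists is not read as evidence by itself.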
